A study of Mus musculus with 6 samples.

How the data were processed

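Gene expression was measured by RNA sequencing of polyadenylated RNA from mouse ear fibroblasts kept for 3 days on glass or on polyacrylamide hydrogels of 1 kPa or 20 kPa, with 2 libraries per group and 6 in all. Groups and replicate numbers were taken from the sample titles, which state the substrate. The labels state that 500000 cells were cultured per sample. They do not state whether the libraries of a group came from separate animals or separate cultures, so the p-values measure only the spread between these samples, which may be technical.

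The values are whole-number counts per gene, deposited as raw counts with no normalisation. Trim Galore, cutadapt, STAR 2.7.10b, featureCounts and the mm10 build are named per the submitters' processing notes. Their settings, the gene annotation behind the counts and whether strand was used in counting are not given in the sources used here, so reads from overlapping genes and from near-identical gene copies are treated as uncertain. The table held 57010 Ensembl gene identifiers. Of these, 91.3% matched an identifier of GENCODE release M21 (GRCm38, the same assembly as mm10), from which symbols and positions were taken. In 99.9% of matches the identifier in the table carried a later version than in that release, so gene boundaries may differ from those behind the counts.

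Library totals ran from 17669006 to 21350111 counts, at which a floor of 3 counts corresponds to 0.141 to 0.17 CPM, the counts of a gene scaled to a common library size. Intervals and floors cover counting error only, because the labels describe amplified libraries and no molecular identifiers. Genes were kept with the filterByExpr function of edgeR 4.0.16 by group, which left 16093 genes, 98.2% of them with a symbol, and libraries were scaled with TMM factors. CPM values use TMM-scaled library sizes. All 6 libraries entered 1 quasi-likelihood fit (glmQLFit and glmQLFTest, edgeR, R 4.3.3) with group as the only term and 3 residual degrees of freedom, so that the 3 groups share 1 estimate of the spread. The common biological coefficient of variation was 5%. The 3 pairwise contrasts and a test over the 3 groups were run, with Benjamini-Hochberg adjustment over all tested genes and a threshold of 0.05. Every adjusted p of a single gene in the text is from this edgeR quasi-likelihood test with Benjamini-Hochberg adjustment. Errors are the SD of the 2 libraries for CPM. For log2 fold changes, SE stands for the absolute log2 fold change divided by the square root of the quasi-likelihood F. It reflects the strength of the test. For large changes of genes with few counts in a group it can lie below the counting error, so it gives no interval there. A single value compared by permutation between 2 and 2 libraries cannot reach a two-sided exact p below 0.333, so none was tested that way.

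The following choices were made before the data were examined: the test, the filter, 39 gene lists, the alternatives and the rule for the genes named. The lists cover stiffness-response and cytoskeletal genes, chromatin enzymes, cell identity, matrix, cell cycle, stress and inflammation, metabolism, markers of other cells that an ear-skin culture could hold, and 2 lists that reflect RNA content. Each list with at least 3 tested members was tested in each of the 3 contrasts, 117 tests in all, with camera of limma 3.58.1 on log2 CPM (prior count 2) at a preset inter-gene correlation of 0.01, with Benjamini-Hochberg adjustment. The same test with an estimated correlation, and the rotation test fry, which asks whether the members of a list move one way without comparing them with other genes, were alternatives. Members were also counted when adjusted over the list alone.

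Genes were named by this rule. In each contrast, the text may name the 6 genes with the largest rise and the 6 with the largest fall among genes past the threshold that have a symbol of a named gene, a mean of at least 5 CPM in the higher group and no overlap between the libraries of the 2 groups. It may name up to 4 members of each list with the smallest unadjusted p. The genes named in every contrast where they were tested include Ccn1, Ccn2, Ankrd1, Acta2, Tagln, Actb, Cfl1, Ipo9, Xpo6, Col1a1, Col3a1, Ep300, Crebbp, Kat2a, Hdac1, Lmna, Pou3f2, Myt1l, Tubb3 and Mki67. For the genes higher or lower on 20 kPa than on both other substrates, the smaller of both fold changes was taken for each gene, and the 6 with the largest of these are named. Other genes are said to be chosen after their values were seen. Some genes and lists that the rule covers are left out of the text.

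The 2 comparisons against glass share the glass libraries, and the 2 comparisons of 20 kPa share the 20 kPa libraries. Counts of all 6 libraries were therefore simulated without group changes in 20 draws, with 1 spread per gene for all groups, and compared in the same way. The 2 shared libraries were also split between the comparisons, a check chosen after seeing the data. On simulated counts for 1 kPa against glass over 16093 genes, with 50 genes changed at each size, the edgeR fit recovered 34% of the genes changed 1.25-fold, 72% at 1.5-fold, 90% at 2-fold and 100% at 4-fold, and 15 of its 187 calls (8%) were unchanged genes. Of the others, 148 were these changed genes and 24 were the members of a list raised 1.5-fold in the same simulation. For a simulated 20 kPa against glass without changes, the fit called 4 genes. In this comparison without changes, 1 gene list passed camera. For the simulated 1 kPa against glass, 1 list besides the raised one passed. The other lists there may hold some of the singly changed genes, so this is not a count of false calls.

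Alternatives were the size factors of DESeq2 1.42.0 within edgeR, total counts without a composition factor, no filter beyond 1 count in total, a filter of 5 CPM in at least 2 libraries, the DESeq2 Wald test, limma-voom, a robust edgeR fit, the replicate number as a block, removal of the mitochondrially encoded genes, fits of only the 4 libraries compared, an adjusted p of 0.01, an absolute log2 fold change of at least 1, and leaving out each library in turn. A fit without the identifier that took the largest share of counts was chosen after seeing the data. Figures were drawn with matplotlib 3.10.9.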

Results

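RNA from mouse dermal fibroblasts, taken from the ear, was sequenced after 3 days on 3 substrates: glass, a soft polyacrylamide gel of 1 kPa and a stiffer gel of 20 kPa, with 2 libraries each. Polyacrylamide gels are inert hydrogels whose stiffness is set by their crosslinking, and glass is far stiffer than either gel. The series names a biphasic influence of stiffness on the epigenetic state of cells that are reprogrammed into neurons, so both gels were set against glass and against each other. Library totals were 21350111 and 17669006 counts on glass, 21055203 and 17894092 on 1 kPa, and 20238031 and 20256227 on 20 kPa. Mitochondrially encoded genes took at most 1.55% of the counts of a library. An unnamed identifier, ENSMUSG00000119584.1, took 5.10% of the counts of glass replicate 2 and 0.95% to 2.90% of those of the other libraries. Libraries of the same group correlated at 0.992 to 0.993 across genes on the log2 scale, and differed by more than counting noise, with a chi-square per degree of freedom of 6.91 on glass, 2.91 on 1 kPa and 2.78 on 20 kPa. The first principal component held 68.2% of the variance and separated glass from both gels, and the second held 16.1% and separated the gels. The 3 groups differed for 8247 of 16093 tested genes (51.2%).

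**Figure D1:**
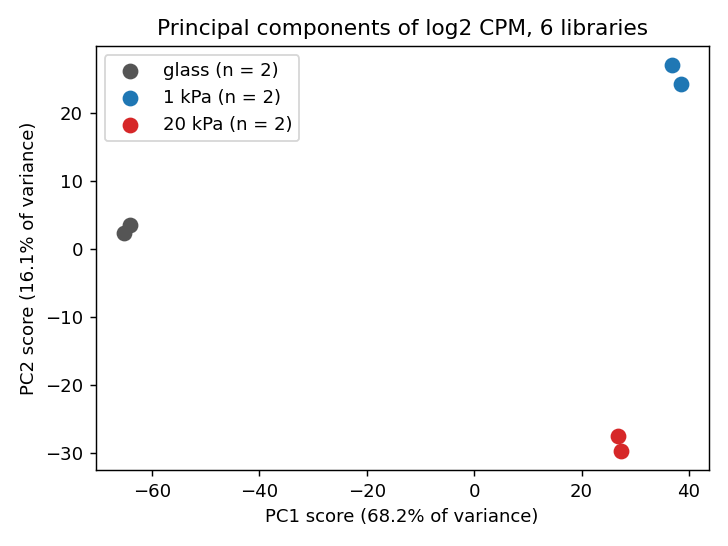
Principal components of log2 CPM over the tested genes, 1 point per library and 2 libraries per substrate; the axes are component scores without units, with the percentage of variance. Glass lies at -64.04 and -65.29 on the first component and the gel libraries between 26.72 and 38.45, and the second component holds 1 kPa at 24.33 and 27.04 and 20 kPa at -29.77 and -27.53.

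Genes that recur below lie at these GRCm38 positions, and their values are counts over their annotated exons. Lcn2 (ENSMUSG00000026822.15) spans chromosome 2 from 32384633 to 32388252 on the minus strand, and Mmp3 (ENSMUSG00000043613.9) spans chromosome 9 from 7445822 to 7455975 on the plus strand. Acta2 (ENSMUSG00000035783.10) spans chromosome 19 from 34241090 to 34255590, and Mki67 (ENSMUSG00000031004.9) chromosome 7 from 135689784 to 135716361, both on the minus strand. Hmgcs1 (ENSMUSG00000093930.3) spans chromosome 13 from 119690379 to 119708260, and Car9 (ENSMUSG00000028463.15) chromosome 4 from 43506966 to 43513729, both on the plus strand. Col2a1 (ENSMUSG00000022483.18) spans chromosome 15 from 97975602 to 98004695 on the minus strand. All are protein-coding in GENCODE M21.

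On 1 kPa, inflammatory and matrix-degrading genes rose strongly against glass, while contractile, mitotic and cholesterol synthesis genes fell. Lcn2, a siderophore-binding protein of innate immunity, rose from 3.61 ± 0.26 CPM on glass to 1190 ± 22 CPM on 1 kPa (mean ± SD, n = 2; log2 fold change 8.35, SE 0.09, edgeR adjusted p = 5.8e-33). Mmp3, the metalloproteinase stromelysin, rose from 29.1 ± 0.32 to 6410 ± 68 CPM (7.78, SE 0.08). Acta2, the smooth muscle actin of contractile fibroblasts, fell from 792 ± 3.6 to 311 ± 19 CPM (-1.35, SE 0.06), and Hmgcs1, an early enzyme of cholesterol synthesis, from 180 ± 1.9 to 55.1 ± 0.42 CPM (-1.71, SE 0.06). In all, 7238 genes changed, 3697 higher and 3541 lower on 1 kPa, of which 1549 and 485 changed at least 2-fold. With total counts in place of TMM the split was 3509 higher and 3599 lower (49.4% higher against 51.1%). Over all 16093 tested genes, the libraries of the 2 groups did not overlap for 11429, where unrelated values would not overlap with a probability of 0.333.

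The 6 named genes with the largest rises were Saa1, Nos2, Mmp13, Lcn2, Mmp12 and Mmp3. Nos2, the inducible nitric oxide synthase, rose from 0.104 ± 0.017 to 131 ± 2.6 CPM (log2 fold change 10.23, SE 0.18), and Mmp13, a collagenase, from 0.504 ± 0.19 to 240 ± 11 CPM (8.92, SE 0.14). Nos2 on glass lay below the floor of 3 counts in a library (0.141 to 0.17 CPM), so the size of its rise is uncertain. For both genes the SE is smaller than the counting error on glass. Saa1, an acute-phase protein, had 0 counts on glass and was at least 101-fold higher on 1 kPa, over a floor of 3 counts for the group; it has a near-identical neighbour, Saa2, and is uncertain. Mmp12 was higher by a ratio of 276 (95% counting interval 49 to 10900). The largest falls were those of Cpa4, Klhdc7a, Erfe, Syt8, Serpinb9b and Myh11, with log2 fold changes from -3.65 (SE 0.27) for Cpa4 to -2.63 (SE 0.21) for Myh11, a smooth muscle myosin.

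Of 39 gene lists, 23 passed camera with the preset correlation for 1 kPa against glass, 11 up and 12 down, and none of the 39 passed with an estimated correlation, where 9 had an unadjusted p under 0.05; fry called 33. Counts of members adjusted over the list alone were the same as those over all genes except where given. All 25 measured chemokine and inflammatory genes rose (median log2 fold change 2.35, camera adjusted p = 2.72e-16, adjusted p = 0.12 with an estimated correlation). Saa3 rose from 12.6 ± 0.77 to 1860 ± 120 CPM, the chemokine Cxcl1 from 53.2 ± 1.1 to 597 ± 2.8 CPM and the cytokine Lif from 9.41 ± 1.1 to 145 ± 1.9 CPM. Macrophage and leukocyte markers did not pass (4 of 9 rose, 0 fell, camera adjusted p = 0.443). The levels of Cd14 were 5.26 ± 0.47 and 42.5 ± 1.7 CPM. Of 26 interferon-stimulated genes, 21 rose and 1 fell (21 and 2 adjusted over the list alone, median 1.04, camera adjusted p = 3.52e-07, adjusted p = 0.14 with an estimated correlation). Among them were Oasl2 (2.01, SE 0.12) and Ifi44 (2.20, SE 0.15). Of 23 immediate early genes, which respond within minutes to stimulation, 12 rose and 6 fell (median 0.26, camera adjusted p = 0.0413, adjusted p = 0.66 with an estimated correlation). This call was lost without glass replicate 2 (0.121) or 1 kPa replicate 1 (0.054).

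Matrix genes rose on 1 kPa. Of 22 matrix-degrading enzymes and their inhibitors, 18 rose and 3 fell (median 1.22, camera adjusted p = 3.9e-06, adjusted p = 0.27 with an estimated correlation). The levels of Mmp11 were 51.1 ± 0.023 and 196 ± 7.7 CPM. Of 27 collagens and fibre-forming matrix genes, 19 rose and 5 fell (median 0.40, camera adjusted p = 0.000576, adjusted p = 0.57 with an estimated correlation). Eln, which encodes elastin, rose by 2.81 (SE 0.07) and the tenascin Tnc by 1.52 (SE 0.07) on the log2 scale, while Col1a1 and Col3a1, the main fibrillar collagens, rose by 0.33 (SE 0.07) and 1.10 (SE 0.07). Of 20 proteoglycan and basement membrane genes, 13 rose and 5 fell (median 0.56, camera adjusted p = 0.0115, adjusted p = 0.34 with an estimated correlation). The small proteoglycan Dcn rose from 157 ± 19 to 3540 ± 320 CPM. The TGF-beta response list did not pass (11 of 20 rose, 6 fell; 12 and 6 adjusted over the list alone, camera adjusted p = 0.0683). The fibroblast identity list did not pass either (11 of 21 rose, 6 fell; 12 and 6 adjusted over the list alone, camera adjusted p = 0.14), though Pi16 rose by 5.15 (SE 0.16).

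Genes of the contractile cytoskeleton fell on 1 kPa. Of 24 MRTF/SRF targets and contractile genes, which respond to actin polymerisation, 22 fell and 1 rose (22 and 2 adjusted over the list alone, median -0.93, camera adjusted p = 1.01e-09, adjusted p = 0.23 with an estimated correlation). Cald1 fell from 1260 ± 0.13 to 588 ± 11 CPM and Cnn2 from 609 ± 9.5 to 262 ± 2.2 CPM. Tagln fell by 1.18 (SE 0.25) at 4.37 ± 0.88 CPM on glass, and is uncertain because 67.9% of its exonic length overlaps other genes. Of 20 genes of actin monomers, cofilin and nuclear actin transport, 13 fell and 3 rose (median -0.31, camera adjusted p = 0.02, adjusted p = 0.27 with an estimated correlation). Actb fell by 0.67 (SE 0.06) and Cfl1, the actin-severing cofilin, by 0.43 (SE 0.06), while the nuclear actin exporter Xpo6 had a log2 fold change of 0.12 (SE 0.06, edgeR adjusted p = 0.098). The nuclear actin importer Ipo9 fell by 0.16 (SE 0.06, edgeR adjusted p = 0.036), a call lost with DESeq2, with the stricter filter, or without any library but glass replicate 2 (0.055 to 0.29). Of 14 nuclear lamina and LINC complex genes, 9 fell and 2 rose (median -0.41, camera adjusted p = 0.00648, adjusted p = 0.34 with an estimated correlation). Lmna, which encodes lamin A/C, fell by 0.39 (SE 0.06). YAP/TAZ targets moved both ways and did not pass (7 of 22 rose, 12 fell, camera adjusted p = 0.143). Ccn1 fell by 0.61 (SE 0.06) and Ankrd1 by 0.97 (SE 0.14), whereas Ccn2 rose by 0.60 (SE 0.06), with 23.2% of its exonic length overlapped, and Igfbp3 by 3.08 (SE 0.07). Integrin and focal adhesion genes did not pass (5 of 23 rose, 10 fell; 6 and 10 adjusted over the list alone, median -0.07 and mean 0, test downwards, camera adjusted p = 0.443).

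Cholesterol synthesis and cell division genes fell together on 1 kPa, and glycolysis genes rose. All 23 cholesterol synthesis genes fell (median -1.44, camera adjusted p = 2.45e-15, adjusted p = 0.12 with an estimated correlation). Insig1, a regulator of this pathway, fell by 1.61 (SE 0.07). All 25 G2/M phase genes fell (median -0.72, camera adjusted p = 9.31e-12, adjusted p = 0.16 with an estimated correlation). The proliferation marker Mki67 was at 296 ± 2.4 and 180 ± 4.5 CPM. Of 25 S phase genes, 13 fell and 0 rose (median -0.20, camera adjusted p = 0.00412, adjusted p = 0.2 with an estimated correlation). Of 22 p53 targets and cell cycle inhibitors, 16 fell and 3 rose (17 and 3 adjusted over the list alone, median -0.55, camera adjusted p = 8.03e-05, adjusted p = 0.16 with an estimated correlation). Of 25 glycolysis and hypoxia genes, 23 rose and 0 fell (24 and 0 adjusted over the list alone, median 0.67, camera adjusted p = 7.26e-10, adjusted p = 0.16 with an estimated correlation). The hypoxia marker Car9 rose from 18.6 ± 0.48 to 167 ± 4.9 CPM and Vegfa, a vascular growth factor, from 121 ± 0.55 to 383 ± 7.7 CPM. All 26 cytosolic ribosomal protein genes fell (median -0.42, camera adjusted p = 2.59e-08, adjusted p = 0.36 with an estimated correlation), though their counts, like those of Actb, are uncertain because of pseudogene copies. Of 12 mitochondrially encoded genes, none passed edgeR, DESeq2 or limma-voom, with 1 at an unadjusted edgeR p under 0.05 (camera adjusted p = 0.829).

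None of the 5 lists of chromatin enzymes passed on 1 kPa. Of 16 histone acetyltransferases, 6 rose and 3 fell (median 0.11, camera adjusted p = 0.611). Crebbp rose from 74.8 ± 3.9 to 90.5 ± 3.5 CPM (0.27, SE 0.07, edgeR adjusted p = 0.001) and Kat2a from 56.4 ± 1.3 to 67.8 ± 2.3 CPM (0.26, SE 0.07, edgeR adjusted p = 0.0022), the latter not without 1 kPa replicate 2 (0.061). Ep300 rose by 0.16 (SE 0.06, edgeR adjusted p = 0.042), a call lost with DESeq2, with total counts, without a filter, and without any library but glass replicate 1 (0.056 to 0.28). Of 18 histone deacetylases, 6 rose and 3 fell (camera adjusted p = 0.507). Hdac9 rose by 2.08 (SE 0.17) and Hdac1 was at -0.09 (SE 0.06, edgeR adjusted p = 0.23). Of 26 histone methyltransferases, 8 rose and 2 fell (camera adjusted p = 0.414), and of 17 histone demethylases, 7 rose and 1 fell (camera adjusted p = 0.258). Kdm7a rose by 1.34 (SE 0.08). Of 12 DNA methylation enzymes, 4 rose and 2 fell (camera adjusted p = 0.401). Tet2, which oxidises methylated cytosine, rose by 0.71 (SE 0.09).

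Neuronal genes were sparse in every group. The labels do not state that these cells received reprogramming factors, and the neuronal factors Pou3f2 and Myt1l stayed below the filter, with 0 to 1 and 0 to 3 counts per library. Of 25 neuronal genes 12 were measured, of which 3 rose and 4 fell on 1 kPa (median 0.03 and mean 0.02, test downwards, camera adjusted p = 0.737). Tubb3, a neuronal tubulin also found in fibroblasts, fell from 36 ± 0.68 to 19.3 ± 0.25 CPM (-0.90, SE 0.09), and the adhesion molecule Nrcam rose by 1.28 (SE 0.15). All 6 measured mesenchymal-to-epithelial genes fell on 1 kPa (median -1.30, camera adjusted p = 0.00374, adjusted p = 0.34 with an estimated correlation). Among them were Tjp1 (-0.64, SE 0.06) and Krt19 (-0.51, SE 0.13).

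Markers of other cells also differed between 1 kPa and glass. Of 14 chondrocyte markers, 9 rose and 3 fell (median 0.90, camera adjusted p = 0.0162, adjusted p = 0.34 with an estimated correlation). The levels of Col11a2 were 12.4 ± 0.79 and 108 ± 8.3 CPM and Comp at 47.9 ± 6.1 and 156 ± 4.8 CPM. Of 9 skeletal muscle markers, 8 rose (median 2.84, camera adjusted p = 7.54e-05, adjusted p = 0.16 with an estimated correlation). The embryonic myosin Myh3 rose from 0.156 ± 0.025 to 6.45 ± 0.73 CPM. Of 10 Schwann cell and melanocyte markers, 7 rose (median 1.20, camera adjusted p = 0.000389, adjusted p = 0.16 with an estimated correlation), and of 14 endothelial markers, 9 rose and 1 fell (median 0.89, camera adjusted p = 0.00227, adjusted p = 0.23 with an estimated correlation). Of 9 keratinocyte markers, 5 fell and 1 rose (6 and 1 adjusted over the list alone, median -2.07, camera adjusted p = 0.0126, adjusted p = 0.31 with an estimated correlation). The levels of Krt5 were 2.68 ± 0.39 and 0.133 ± 0.05 CPM. Pericyte and vascular smooth muscle markers did not pass (8 of 12 rose, 2 fell, camera adjusted p = 0.112).

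The 20 kPa gel was set against glass to ask whether an intermediate stiffness changes the same groups of genes. On 20 kPa, cholesterol synthesis, mitotic and contractile genes again fell, matrix genes rose, and inflammatory genes rose, most of them to lower levels than on 1 kPa. Lcn2 reached 293 ± 1.1 CPM against 3.61 ± 0.26 CPM on glass (mean ± SD, n = 2; log2 fold change 6.34, SE 0.09, edgeR adjusted p = 1.2e-29). Acta2 fell from 792 ± 3.6 to 380 ± 9.1 CPM (-1.06, SE 0.06), Hmgcs1 from 180 ± 1.9 to 61.1 ± 0.92 CPM (-1.56, SE 0.06) and Mki67 from 296 ± 2.4 to 148 ± 2.9 CPM (-1, SE 0.06). In all, 6732 genes changed, 3582 higher and 3150 lower on 20 kPa, of which 1369 and 481 changed at least 2-fold. With total counts 3827 were higher and 2655 lower (59% higher against 53.2%). The libraries of both groups did not overlap for 10865 of all tested genes, against the same probability of 0.333.

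Among the largest rises on 20 kPa were those of Fcgr2b (log2 fold change 7.04, SE 0.30), Mmp13 (6.50, SE 0.16), Lcn2 and Saa3 (5.71, SE 0.08). Fcgr2b encodes an inhibitory receptor for antibodies. The largest falls were those of Myh11 (-3.71, SE 0.24), Erfe, Serpinb9b, Gfra2, Mbp and F2rl1 (-2.41, SE 0.13). Gfra2, a receptor for a glial growth factor, fell from 25.7 ± 0.56 to 4.27 ± 0.67 CPM.

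Again 23 of 39 lists passed camera for 20 kPa against glass, 10 up and 13 down, none with an estimated correlation, where 11 had an unadjusted p under 0.05; fry called 32. Of 25 chemokine and inflammatory genes, 19 rose and 1 fell (median 1.15, and 1.12 with Il1b and Csf2, which had at most 3 counts in a group, set at the floor, camera adjusted p = 2.06e-09, adjusted p = 0.14 with an estimated correlation). Complement C3 rose from 407 ± 35 to 2250 ± 90 CPM. Of 26 interferon-stimulated genes, 19 rose and 0 fell (21 and 0 adjusted over the list alone, median 0.79, camera adjusted p = 8.24e-07, adjusted p = 0.14 with an estimated correlation). Macrophage and leukocyte markers did not pass (2 of 9 rose, 1 fell, camera adjusted p = 0.535). Of 22 matrix-degrading enzymes and their inhibitors, 18 rose and 3 fell (median 1.02, camera adjusted p = 2.78e-06, adjusted p = 0.27 with an estimated correlation), and of 27 collagens and fibre-forming matrix genes, 21 rose and 4 fell (median 0.37, camera adjusted p = 9.15e-05, adjusted p = 0.51 with an estimated correlation). Eln rose from 24.2 ± 0.65 to 472 ± 7.9 CPM, Col3a1 by 1.48 (SE 0.07) and Col1a1 by 0.37 (SE 0.07). Of 20 proteoglycan and basement membrane genes, 13 rose and 3 fell (14 and 3 adjusted over the list alone, median 0.83, camera adjusted p = 0.00218, adjusted p = 0.28 with an estimated correlation), and of 20 TGF-beta response genes, 13 rose and 6 fell (14 and 6 adjusted over the list alone, median 0.43, camera adjusted p = 0.0177, adjusted p = 0.43 with an estimated correlation). The fibroblast identity list did not pass (12 of 21 rose, 5 fell, camera adjusted p = 0.0992).

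Cytoskeletal genes fell on 20 kPa too. Of 24 MRTF/SRF targets and contractile genes, 23 fell and 1 rose (median -0.82, camera adjusted p = 3.7e-11, adjusted p = 0.22 with an estimated correlation). Zyx, a focal adhesion protein, fell from 688 ± 30 to 283 ± 5.5 CPM. Tagln fell by 1.08 (SE 0.24) and is uncertain as above. Of 22 YAP/TAZ targets, 15 fell and 5 rose (median -0.38, camera adjusted p = 0.00516, adjusted p = 0.51 with an estimated correlation). Ccn1 fell by 0.71 (SE 0.06) and Ankrd1 by 1.51 (SE 0.15), while Ccn2 rose by 0.75 (SE 0.06) and Tgfb2 by 1.98 (SE 0.10). Of 20 actin monomer, cofilin and nuclear actin transport genes, 12 fell and 2 rose (13 and 2 adjusted over the list alone, median -0.28, camera adjusted p = 0.00513, adjusted p = 0.23 with an estimated correlation). Actb fell by 0.64 (SE 0.06) and Cfl1 by 0.39 (SE 0.06). Xpo6 had a log2 fold change of -0.15 (SE 0.06, edgeR adjusted p = 0.052; 0.036 without glass replicate 2, and past the threshold with 3 other settings). Ipo9 fell by 0.18 (SE 0.06, edgeR adjusted p = 0.019), a call lost with total counts or without either 20 kPa library or glass replicate 1 (0.057 to 0.18). Of 14 nuclear lamina and LINC complex genes, 11 fell and 0 rose (11 and 1 adjusted over the list alone, median -0.42, camera adjusted p = 0.000745, adjusted p = 0.27 with an estimated correlation). Lmna fell by 0.37 (SE 0.06). Integrin and focal adhesion genes did not pass (5 of 23 rose, 9 fell, camera adjusted p = 0.36).

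All 23 cholesterol synthesis genes fell on 20 kPa (median -1.42, camera adjusted p = 8.91e-17, adjusted p = 0.12 with an estimated correlation). All 25 G2/M phase genes fell (median -1, camera adjusted p = 4.89e-15, adjusted p = 0.16 with an estimated correlation), as did 18 of 25 S phase genes, with 0 rising (median -0.37, camera adjusted p = 1.06e-05, adjusted p = 0.16 with an estimated correlation). Of 22 p53 targets and cell cycle inhibitors, 17 fell and 4 rose (median -0.51, camera adjusted p = 7.54e-05, adjusted p = 0.16 with an estimated correlation). Cdkn1a, the inhibitor p21, fell from 291 ± 9.6 to 150 ± 0.91 CPM. All 26 ribosomal protein genes fell (median -0.41, camera adjusted p = 4.79e-09, adjusted p = 0.34 with an estimated correlation), and 1 of 12 mitochondrially encoded genes rose (0 adjusted over the list alone, camera adjusted p = 0.989). This gene, mt-Nd2, no longer passed with DESeq2 (adjusted p = 0.37), its size factors, the robust edgeR fit or a replicate block (0.055 to 0.068). It did not pass either without glass replicate 1, 1 kPa replicate 2 or either 20 kPa library (edgeR adjusted p = 0.064 to 0.35). Glycolysis and hypoxia genes did not pass (9 of 25 rose, 10 fell; median -0.06 and mean 0.14, test downwards, camera adjusted p = 0.683). Car9 rose by 1.86 (SE 0.07) and the gene of the vasodilator adrenomedullin, Adm, fell by 0.92 (SE 0.07). Immediate early genes did not pass either (9 of 23 rose, 10 fell; median -0.04 and mean 0.06, test downwards, camera adjusted p = 0.677).

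Among chromatin enzymes on 20 kPa, 4 of 16 histone acetyltransferases rose and 2 fell (camera adjusted p = 0.936), with Ep300 at -0.03 (SE 0.06), Crebbp at 0.03 (SE 0.07) and Kat2a at 0.04 (SE 0.07), none of these past the edgeR threshold. Of 18 histone deacetylases, 3 rose and 1 fell (2 and 1 adjusted over the list alone, camera adjusted p = 0.655), with Hdac1 at -0.08 (SE 0.06, edgeR adjusted p = 0.3). Of 26 histone methyltransferases, 1 rose and 3 fell (1 and 0 adjusted over the list alone, median 0.01 and mean -0.01, test downwards, camera adjusted p = 0.688), and of 17 histone demethylases, 4 rose and 3 fell (camera adjusted p = 0.509). Of 12 DNA methylation enzymes, 5 rose and 4 fell (6 and 4 adjusted over the list alone, camera adjusted p = 0.872). The methylation cofactor Uhrf1 fell by 0.51 (SE 0.07) and the methyltransferase Dnmt3a rose by 0.48 (SE 0.08). Neuronal genes did not pass (3 of 12 rose, 4 fell; median -0.20 and mean 0.19, test downwards, camera adjusted p = 0.677). Tubb3 fell by 0.79 (SE 0.09). Mesenchymal-to-epithelial genes did not pass (4 of 6 fell, camera adjusted p = 0.0788), though they did without 20 kPa replicate 1 (0.047) or 20 kPa replicate 2 (0.0328).

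Of 14 chondrocyte markers, 13 rose and 1 fell on 20 kPa (median 2.04, camera adjusted p = 8.47e-08, adjusted p = 0.16 with an estimated correlation). Col9a3 rose from 19.2 ± 2 to 149 ± 1.9 CPM. Of 9 skeletal muscle markers, 6 rose (median 2.15, camera adjusted p = 0.00345, adjusted p = 0.22 with an estimated correlation), and of 10 Schwann cell and melanocyte markers, 9 rose (median 1.63, camera adjusted p = 8.03e-05, adjusted p = 0.16 with an estimated correlation). The levels of Cdh19 were 0.788 ± 0.53 and 9.98 ± 0.28 CPM. Of 14 endothelial markers, 11 rose (11 rose and 1 fell adjusted over the list alone, median 0.84, camera adjusted p = 0.000487, adjusted p = 0.2 with an estimated correlation). Of 9 keratinocyte markers, 6 fell and 1 rose (median -2.08, camera adjusted p = 0.00648, adjusted p = 0.28 with an estimated correlation). Pericyte and vascular smooth muscle markers did not pass (5 of 12 rose, 3 fell, camera adjusted p = 0.414).

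The log2 fold changes of both gels against glass were similar across genes, with a Pearson r of 0.866 over 16093 genes, which are not independent replicates. Unchanged groups simulated with glass libraries shared by both comparisons gave a mean r of 0.506 and at most 0.528. The simulation gave all groups the same spread per gene. The real glass libraries differed more from each other than those of 1 kPa or 20 kPa (SD of the log2 difference 0.373 against 0.335 and 0.336). The r without changes may therefore be higher than simulated. The covariance was 0.731 against 0.028 in the simulation, a difference of 0.703. Both gels were higher than glass for 2636 genes and lower for 2452, where independent lists would share 823 and 693. The simulation shared 0.2 and 0.05 on average. With no changed genes it calls few, so it gives no expected overlap for lists of the observed size. With a separate glass library for each gel, a split made after the results were seen, r was 0.745 and 0.735 for the 2 ways to assign them. The genes higher on both gels then numbered 2171 and 2090, and the genes lower on both 2164 and 1970. Each comparison then holds 1 glass library, and part of the excess in the full comparison may come from the shared libraries.

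**Figure D2:**
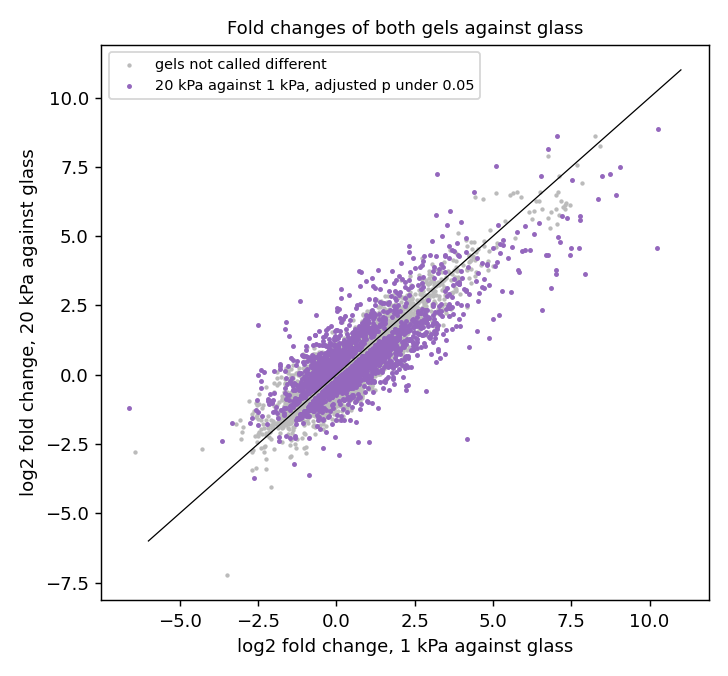
Log2 fold change of each tested gene on 20 kPa against glass (vertical axis) over that on 1 kPa against glass (horizontal axis), with a line of equal change; both use the same glass libraries. Purple points mark the 3035 genes that differed between the gels at an adjusted p under 0.05, and r across genes is 0.866.

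Both gels are polyacrylamide and differ in stiffness, which is set by crosslinking, so they were compared directly. Inflammatory, hypoxia and immediate early genes were lower on 20 kPa than on 1 kPa, and chondrocyte markers were higher. Nos2 fell from 131 ± 2.6 CPM on 1 kPa to 2.58 ± 0.36 CPM on 20 kPa (mean ± SD, n = 2; log2 fold change -5.67, SE 0.11, edgeR adjusted p = 8.8e-26), and Cxcl1 from 597 ± 2.8 to 127 ± 2.1 CPM (-2.24, SE 0.06). Ogn, a small leucine-rich proteoglycan, rose from 68.5 ± 5.8 to 310 ± 11 CPM (2.18, SE 0.09), and Col2a1, the main collagen of cartilage, from 274 ± 9.3 to 518 ± 18 CPM (0.92, SE 0.06). In all, 3035 genes changed, 1438 higher and 1597 lower on 20 kPa, of which 218 and 281 changed at least 2-fold. The libraries of both groups did not overlap for 9666 of all tested genes, against a probability of 0.333 for unrelated values. With total counts in place of TMM the split was 1945 higher and 1253 lower (60.8% higher against 47.4%). The count fell to 2022 with DESeq2, to 1910 without 1 kPa replicate 1, 1680 without 1 kPa replicate 2, 1798 without 20 kPa replicate 1 and 1870 without 20 kPa replicate 2.

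**Figure D3:**
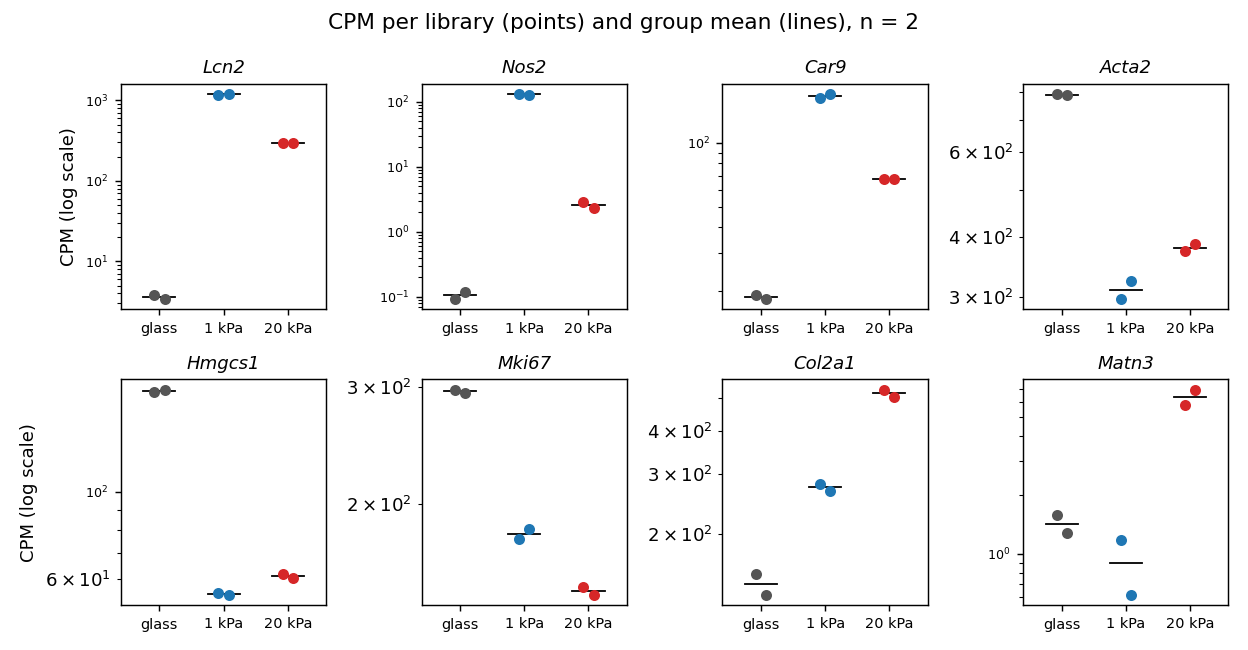
CPM of 8 genes on a log scale, with a point per library and a line at the mean of the 2 libraries of each substrate. Lcn2, Nos2 and Car9 are highest on 1 kPa, Acta2, Hmgcs1 and Mki67 are highest on glass, and Col2a1 and Matn3 are highest on 20 kPa, at 518 and 6.36 CPM.

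The largest named rises on 20 kPa over 1 kPa were those of Matn3 (log2 fold change 2.80, SE 0.28), Fam198a (2.62, SE 0.23), Aldh1a7 (5.83 ± 0.39 to 35.2 ± 1.4 CPM), C1qtnf3 (2.45, SE 0.19), Chrdl2 (2.43, SE 0.25) and Omd (2.42, SE 0.15). Matn3 encodes a cartilage matrilin and Omd the proteoglycan osteomodulin. The largest falls were those of Nos2, Csf3 (-4.22, SE 0.12), Vnn3 (-3.24, SE 0.20), Cxcl2 (-2.97, SE 0.10), Mmp13 (-2.42, SE 0.07) and Cxcl1. Csf3, which encodes the granulocyte growth factor G-CSF, fell from 56.3 ± 3.5 to 3.01 ± 0.055 CPM.

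For 20 kPa against 1 kPa, 13 of 39 lists passed camera, 2 up and 11 down, none with an estimated correlation, where 6 had an unadjusted p under 0.05; fry called 18. Of 25 glycolysis and hypoxia genes, 24 fell and 0 rose (24 and 1 adjusted over the list alone, median -0.72, camera adjusted p = 3.91e-20, adjusted p = 0.14 with an estimated correlation). Car9 fell from 167 ± 4.9 to 67.8 ± 0.13 CPM and the oxygen sensor Egln3 from 31.3 ± 1.9 to 8.43 ± 0.35 CPM. Of 25 chemokine and inflammatory genes, 22 fell and 2 rose (23 and 2 adjusted over the list alone, median -1.50, camera adjusted p = 1.28e-17, adjusted p = 0.12 with an estimated correlation). The 2 that rose, Vcam1 (0.24, SE 0.06) and Il33 (0.38, SE 0.11), were looked up after their values were seen. Of 23 immediate early genes, 19 fell and 0 rose (19 and 1 adjusted over the list alone, median -0.33, camera adjusted p = 3.61e-09, adjusted p = 0.27 with an estimated correlation). Ier3 fell by 1.12 (SE 0.06) and Nr4a1 by 0.84 (SE 0.06). Of 26 interferon-stimulated genes, 13 fell and 3 rose (median -0.38, camera adjusted p = 0.00202, adjusted p = 0.18 with an estimated correlation). Ifit3 rose by 1.01 (SE 0.12). Of 25 G2/M phase genes, 12 fell and 0 rose (15 and 0 adjusted over the list alone, median -0.23, camera adjusted p = 3.6e-06, adjusted p = 0.26 with an estimated correlation). With total counts 8 of the 25 fell, and with a library left out the median ran from -0.26 to -0.20. Mki67 fell by 0.28 (SE 0.06). Of 25 S phase genes, 2 fell and 0 rose (median -0.16, camera adjusted p = 0.00516, adjusted p = 0.2 with an estimated correlation). Of 14 chondrocyte markers, 13 rose and 0 fell (median 0.81, camera adjusted p = 3.7e-11, adjusted p = 0.16 with an estimated correlation). Acan, the aggregating proteoglycan of cartilage, rose from 102 ± 0.85 to 213 ± 11 CPM. Of 9 skeletal muscle markers, 5 fell (7 adjusted over the list alone, median -0.79, camera adjusted p = 0.000238, adjusted p = 0.16 with an estimated correlation). The levels of Des were 9.16 ± 0.35 and 3.16 ± 0.083 CPM. Of 12 pericyte and vascular smooth muscle markers, 5 fell and 1 rose (median -0.29, camera adjusted p = 0.0283, adjusted p = 0.27 with an estimated correlation), a call lost without glass replicate 1 (0.0562) or glass replicate 2 (0.0549).

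Cholesterol synthesis and cytoskeletal lists did not pass between the gels. Of 23 cholesterol synthesis genes, 1 rose and 1 fell (median -0.02, and 0.025 with total counts, camera adjusted p = 0.667). Hmgcs1 was at 0.15 (SE 0.06, edgeR adjusted p = 0.11). Of 24 MRTF/SRF targets and contractile genes, 7 rose and 3 fell (7 and 5 adjusted over the list alone, camera adjusted p = 0.319). Acta2 rose by 0.29 (SE 0.06, edgeR adjusted p = 0.00042), though not without 1 kPa replicate 1 (0.064), and Tagln was at 0.10 (SE 0.28). Of 22 YAP/TAZ targets, 2 rose and 8 fell (4 and 10 adjusted over the list alone, camera adjusted p = 0.0943). Ccn1 was at -0.10 (SE 0.06) and Ccn2 at 0.15 (SE 0.06, edgeR adjusted p = 0.07; 0.0074 without either glass library, and past the threshold with 3 other settings). Ankrd1 fell by 0.54 (SE 0.16, edgeR adjusted p = 0.021), a call lost with DESeq2 or without any gel library but 1 kPa replicate 1 (0.069 to 0.22). The actin list (2 of 20 rose, 4 fell, camera adjusted p = 0.779), lamina genes (0 of 14 rose, 2 fell; 0.33) and integrins (3 of 23 rose, 4 fell; 5 and 6 adjusted over the list alone; 0.393) did not pass. Actb was at 0.02 (SE 0.06), Cfl1 at 0.04 (SE 0.06), Ipo9 at -0.02 (SE 0.06) and Lmna at 0.02 (SE 0.06), none past the edgeR threshold, and Xpo6 fell by 0.27 (SE 0.06). Of 26 ribosomal protein genes and of 12 mitochondrially encoded genes, 0 passed edgeR, DESeq2 or limma-voom, with 2 and 1 at an unadjusted edgeR p under 0.05 (ribosomal median 0.02 and mean 0, test downwards, camera adjusted p = 0.99 and 0.703).

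Matrix and identity lists also did not pass between the gels. Of 27 collagens and fibre-forming matrix genes, 6 rose and 9 fell (8 and 9 adjusted over the list alone, median -0.07 and mean 0.02, test downwards, camera adjusted p = 0.556). Eln rose by 1.47 (SE 0.06) and Col3a1 by 0.38 (SE 0.07), and Col1a1 was at 0.03 (SE 0.07). Of 22 matrix-degrading enzymes and their inhibitors, 5 rose and 12 fell (7 and 12 adjusted over the list alone, camera adjusted p = 0.168), and of 20 proteoglycan and basement membrane genes, 6 rose and 7 fell (7 and 8 adjusted over the list alone, median -0.06 and mean 0.24, test upwards, camera adjusted p = 0.938). TGF-beta response genes (4 of 20 rose, 5 fell, camera adjusted p = 0.707), p53 targets (6 of 22 rose, 3 fell; 7 and 3 adjusted over the list alone; 0.338), fibroblast identity genes (6 of 21 rose, 5 fell; 7 and 6 adjusted over the list alone; 0.556), mesenchymal-to-epithelial genes (2 of 6 rose, 1 fell; 0.393) and neuronal genes (3 of 12 rose, 1 fell; 0.427) did not pass. Tubb3 was at 0.11 (SE 0.09, edgeR adjusted p = 0.44), and the adhesion molecule L1cam rose by 0.76 (SE 0.12). Endothelial markers (2 of 14 rose, 3 fell, camera adjusted p = 0.677), Schwann cell and melanocyte markers (2 of 10 rose, 2 fell; median -0.11 and mean 0.04, test upwards; 0.87) and leukocyte markers (0 of 9 rose, 1 fell; 0.306) did not pass. Of 9 keratinocyte markers, 0 passed edgeR, DESeq2 or limma-voom, with 3 at an unadjusted edgeR p under 0.05 (camera adjusted p = 0.482).

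Among chromatin enzymes, 3 of 16 histone acetyltransferases fell on 20 kPa against 1 kPa and 0 rose (3 and 1 adjusted over the list alone, median 0 and mean -0.01, test downwards, camera adjusted p = 0.721). Crebbp fell by 0.24 (SE 0.06, edgeR adjusted p = 0.0069), though not without 1 kPa replicate 2 or 20 kPa replicate 2 (0.11 to 0.17). Kat2a fell by 0.23 (SE 0.07, edgeR adjusted p = 0.018), though not with total counts or without any 1 of the 4 gel libraries (0.071 to 0.24). Ep300 fell by 0.18 (SE 0.06, edgeR adjusted p = 0.036), though not with DESeq2, with total counts, without a filter, or without either 1 kPa library or 20 kPa replicate 2 (0.14 to 0.4). Of 18 histone deacetylases, 1 rose and 2 fell (camera adjusted p = 0.675). Hdac7 fell from 211 ± 5 to 153 ± 12 CPM and Hdac1 was at 0.01 (SE 0.06). Of 26 histone methyltransferases, 1 rose and 5 fell (1 and 6 adjusted over the list alone, camera adjusted p = 0.0771), and of 17 histone demethylases, 0 rose and 5 fell (1 and 6 adjusted over the list alone, camera adjusted p = 0.24). Jmjd6 fell by 0.56 (SE 0.07). Of 12 DNA methylation enzymes, 0 rose and 3 fell (camera adjusted p = 0.38). The maintenance methyltransferase Dnmt1 fell by 0.27 (SE 0.06).

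**Figure D4:**
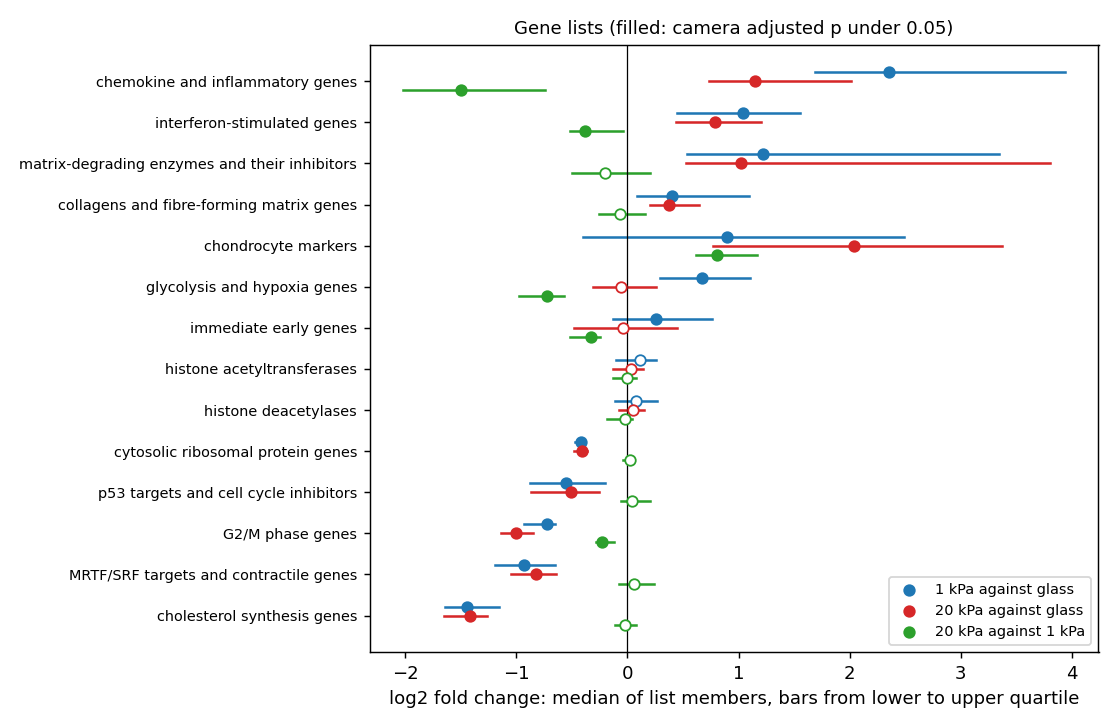
Median log2 fold change of the members of 14 gene lists, with bars from the lower to the upper quartile, for the 3 comparisons; filled points passed camera with the preset correlation. Chemokine and inflammatory genes lie at 2.35 on 1 kPa and 1.15 on 20 kPa against glass, and cholesterol synthesis genes at -1.44 and -1.42; the medians between the gels of cholesterol synthesis, histone acetyltransferase and histone deacetylase genes are negative or 0 with TMM and positive with total counts.

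A biphasic relation would put 20 kPa above or below both other substrates. Glass differs from the gels in material as well as stiffness. An effect of the gel added to a steady change from 1 kPa to 20 kPa can give the same order. The cases cannot be told apart here. Of 14 chondrocyte markers, 12 were highest on 20 kPa, and 12 of 25 G2/M phase genes and 10 of 25 glycolysis and hypoxia genes were lowest there. However, 23 of the 25 glycolysis and hypoxia genes were higher on 1 kPa than on both others. That list did not pass camera for 20 kPa against glass (adjusted p = 0.683). Slc40a1, the iron exporter ferroportin, was at 5.11 ± 0.82 CPM on glass, 5.50 ± 0.47 on 1 kPa and 26.8 ± 0.46 on 20 kPa (mean ± SD, n = 2), and Matn3 was at 1.42 ± 0.21, 0.893 ± 0.39 and 6.36 ± 0.80 CPM. The receptor gene Adcyap1r1 was at 23.2 ± 1.1, 12.6 ± 0.45 and 4.71 ± 0.16 CPM, and Epha1 at 18.4 ± 2.2, 11.9 ± 0.67 and 5.10 ± 0.25 CPM. In all, 687 genes (4.3%) were higher on 20 kPa than on both others and 456 (2.8%) lower, by both edgeR tests. Against the mean of the other groups, 2516 were higher and 2070 lower. That contrast can also call genes that differ from glass alike on both gels, so these are not counts of extremes on 20 kPa.

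The 6 genes with the largest rise over both others were Fam198a, C1qtnf3, Chrdl2, Calml3, Slc40a1 and Matn3, and the 6 with the largest fall were Adcyap1r1, Epha1, Mir6236, Fam169b, Siglecg and Arhgef4. Mir6236 was at 58.3 ± 50, 52.9 ± 30 and 25 ± 5.4 CPM on glass, 1 kPa and 20 kPa, and without glass replicate 2 its log2 fold change on 20 kPa against glass turned from -1.19 to 0.15. The call for Mir6236 on 20 kPa was also lost against glass and against 1 kPa with DESeq2 (adjusted p = 0.31 and 0.51), the robust edgeR fit (0.44 and 0.56) and limma-voom (0.087 and 0.068). It was lost without 20 kPa replicate 1 against glass (0.12), and between the gels without 1 kPa replicate 1 or either 20 kPa library (0.088 to 0.55). Calml3 was at 0.353 ± 0.24, 1.68 ± 0.24 and 8.55 ± 0.79 CPM. Among the 39 lists, tested in both directions with Fisher's exact test (two-sided, 78 tests, Benjamini-Hochberg adjustment, genes taken as independent), 12 of 14 chondrocyte markers were highest on 20 kPa (adjusted p = 2.2e-13), as were 6 of 20 proteoglycan and basement membrane genes (0.0018), 6 of 27 collagens and fibre-forming matrix genes (0.0079) and 5 of 21 fibroblast identity genes (0.014). Lowest on 20 kPa were 12 of 25 G2/M phase genes (adjusted p = 3.4e-11 by Fisher's exact test), 10 of 25 glycolysis and hypoxia genes (1.8e-08), 9 of 23 immediate early genes (1.2e-07), 6 of 22 YAP/TAZ targets (4e-04) and 5 of 20 oxidative stress genes (0.0022). With total counts, 8 G2/M genes were called lower on 20 kPa than on 1 kPa, against 12 with TMM. Higher on 1 kPa than on both others were 23 of the 25 glycolysis and hypoxia genes and 11 of the 23 immediate early genes. Neither of these lists passed camera for 20 kPa against glass (adjusted p = 0.683 and 0.677). Extremes on 1 kPa were not tested by list. Of 16 histone acetyltransferases, 0 were higher or lower on 20 kPa than on both others. Crebbp, Kat2a and Ep300 were higher on 1 kPa than on both others, with the limits given for each above.

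Of the 7238 genes that differed between 1 kPa and glass, 4550 (62.9%) had their 20 kPa mean between the other 2, by the order of the means alone. For 845 of them all 3 differences passed. The 62.9% has no matched expectation, since the genes were selected to differ between 1 kPa and glass. Where the gels do not differ, noise alone can put the 20 kPa mean between the others. Genes higher on 1 kPa than on both others numbered 1066, and genes lower on 1 kPa than on both others 653. Without 1 kPa replicate 1, 1 kPa replicate 2, 20 kPa replicate 1 or 20 kPa replicate 2, the 845 became 547, 530, 482 and 472, and the 653 became 381, 307, 376 and 400. The 1066 became 710 without 1 kPa replicate 1, 686 without 1 kPa replicate 2 and 701 without 20 kPa replicate 2. Groups simulated without effects, with 20 kPa libraries shared by both comparisons, gave on average 0 genes above and 0.25 below both others. With no changed genes few are called, so these counts give no expected overlap for lists of the observed size. Independent lists of the observed size would share 320 and 313. With a separate 20 kPa library for each comparison, split after the results were seen, 419 and 401 genes were above both others and 197 and 204 below. The log2 fold changes of 20 kPa against 1 kPa and against glass then had an r of 0.035 and 0.042. The 320 and 313 belong to the full fit, so the split counts have no matched expectation. Part of the excess in the full comparison may come from the shared libraries. The count above both others was 417 with DESeq2, 435 without 1 kPa replicate 2 and 411 without 20 kPa replicate 1. The count below both others was 290 with total counts, 257 without 1 kPa replicate 1, 217 without 1 kPa replicate 2, 228 without 20 kPa replicate 1 and 226 without 20 kPa replicate 2.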

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

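The 6 tests of explanations and the heterogeneity test Q were chosen only after the results were seen, while the edgeR comparisons were chosen before.

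Some genes moved in opposite directions on the 2 gels. Relative to glass, 48 genes were higher on 1 kPa and lower on 20 kPa, and 60 genes were lower on 1 kPa and higher on 20 kPa. These 108 genes were selected to differ in the edgeR test of 20 kPa against 1 kPa as well, and the 48 became 31 with DESeq2, 25 with total counts and 26 to 30 without any 1 library but glass replicate 2. Adm, which encodes the vasodilator adrenomedullin, was at 82.2 CPM on glass, 110 CPM on 1 kPa and 43.4 CPM on 20 kPa, with a log2 fold change of -1.34 between the gels. The proteoglycan gene Omd was at 12.9, 4.89 and 26.1 CPM, with a log2 fold change of 2.42 between the gels.

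Of 14 chondrocyte markers, 9 rose and 3 fell on 1 kPa against glass, and 13 rose on 20 kPa against 1 kPa, with Col2a1 at 143, 274 and 518 CPM and Comp at 47.9, 156 and 241 CPM (n = 2 per substrate). On 1 kPa, 3 of 14 markers, Sox9, Cnmd and Ucma, fell (named after their values were seen). A larger share of the same chondrocytes would raise each of them if chondrocytes express it above the other cells. Under that condition, which was not analysed, the falls argue against such a share as the whole cause. Between the gels, 13 of 14 markers rose, as a larger share would have it, and they rose unevenly, from a log2 fold change of 0.35 for Sox5 to 2.80 for Matn3 (Q = 263, df 13). More chondrocytes and a change of expression in the fibroblasts therefore cannot be told apart for 20 kPa against 1 kPa, since no value here gives the cell types of a library. None of the 14 markers is in another of the 39 lists, and how many of them dermal fibroblasts express was not analysed here.

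Chemokine and inflammatory genes were 5.23-fold higher in summed CPM on 1 kPa than on glass (2890 ± 37 to 15100 ± 250 CPM, mean ± SD, n = 2). The gel as a material, if equal on both gels, is argued against as the whole cause, because 22 of 25 of these genes fell on 20 kPa against 1 kPa and 2 rose. The list passed both camera and fry between the gels in 9 of 9 settings (3 scalings and each library left out), which share libraries. It already passed with all libraries when this test was set, so the 9 settings add no separate support. The list did not pass camera with an estimated correlation (adjusted p = 0.12). The gels also differ in crosslinking, so stiffness and other differences between them cannot be told apart. More leukocytes on 1 kPa stay open as a source, because the summed CPM of 18 leukocyte markers was 3.07-fold higher (19.5 ± 1.7 to 59.6 ± 0.18 CPM), between the limits set for and against it. Most of that rise was Cd14, at 5.26 and 42.5 CPM, the other 17 markers were 1.21-fold higher in sum (14.2 ± 2.1 to 17.2 ± 1.5 CPM), and the leukocyte marker Ptprc, chosen after its values were seen, had 5 and 5 counts on glass and 2 and 3 on 1 kPa. A response of the fibroblasts to low stiffness and a contribution of the gel also stay open, and neither was tested.

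Cholesterol synthesis and G2/M phase genes were lower on both gels than on glass. For the cholesterol synthesis genes the gel as a material may be the whole cause, since 2 of 23 genes differed between the gels and the list passed both camera and fry in 0 of 9 settings. The G2/M list was lower on 20 kPa than on 1 kPa in 9 of 9 settings by both camera and fry (adjusted p = 3.6e-06 and 0.0069 with all libraries). It did not pass camera with an estimated correlation (adjusted p = 0.26). By single genes 12 of 25 fell and 0 rose (5 without 1 kPa replicate 2, 7 without 20 kPa replicate 2 and 8 with total counts), short of the 13 that a first limit of 0.5 asked for, and the list tests were set after this was known. A lower limit, which asked for 7 genes, was also tried after the counts were known. The list already passed with all libraries when its tests were set, and the 9 settings share libraries. They therefore cannot decide whether the gel is the whole cause of the fall of the G2/M genes. A contribution of the gel to the fall of the G2/M genes stays open, as does a response to stiffness already complete at 20 kPa for the cholesterol synthesis genes, and neither was tested.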

How the results depend on the processing

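The fit without the unnamed identifier ENSMUSG00000119584.1 was chosen only after the data were seen, and the other alternatives were chosen before.

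Over 560 gene tests in 16 settings, 8632 results kept their side of the threshold and, where they passed, their direction. Of the others, 214 no longer passed, 62 newly passed and 2 reversed. A further 50 had no value because the setting removed the gene or gave it no adjusted p. A change of sign counted as a reversal only where the result passed in the main fit or in the setting. Both reversals were of Mir6236 without glass replicate 2, at 1.24 for 1 kPa against glass and 0.15 for 20 kPa against glass (edgeR). Its log2 fold changes ran from -0.86 to 1.24 and from -1.91 to 0.15 when each library was left out. Without ENSMUSG00000119584.1, 7213, 6711 and 3006 genes changed in the 3 comparisons and 59 lists passed. With the replicate number as a block the counts were 7032, 6526 and 2862.

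The correlation of both gels' fold changes was 0.866, and 0.851 with limma-voom, 0.591 without a filter, 0.898 with the stricter filter and 0.79 to 0.875 with a library left out. With an absolute log2 fold change of at least 1, 2034, 1850 and 499 genes changed for 1 kPa against glass, 20 kPa against glass and 20 kPa against 1 kPa, as this threshold asks for more. For 20 kPa against 1 kPa, 3035 genes became 2022 with DESeq2 and 1933 at an adjusted p of 0.01 (edgeR). Leaving out each library gave 1680 to 3824. Genes above both others on 20 kPa numbered 687, 417 with DESeq2 and 411 to 838 with a library left out. Genes below both others numbered 456, 290 with total counts and 217 to 571. Genes above both others on 1 kPa numbered 1066, and 686 to 1192 with a library left out. Genes below both numbered 653, 388 with DESeq2 and 307 to 897. The 845 genes ordered with stiffness in all 3 differences became 472 to 1013. Of the genes that moved in opposite directions on the 2 gels, the 48 became 31 with DESeq2, 25 with total counts and 26 to 46 with a library left out, and the 60 became 40 to 57. The libraries that moved these counts by over 1.5 times are named with their values in the report or above. The 59 list calls of camera became 0 with an estimated correlation, where 26 had an unadjusted p under 0.05, and 83 with fry. For DESeq2, limma-voom, the filters and total counts, the cause was not tested. With a library left out, the lone sample was assumed to vary like the other groups, and fewer samples were fitted.

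Apart from the fold change threshold, the counts for each gel against glass, for any difference among the 3 groups, for both gels against glass and for 20 kPa means between the others stayed within 1.5 times of the reported value in the settings run. With a library left out, these were 5569 to 6997 genes for 1 kPa and 5118 to 6442 for 20 kPa against glass, 2178 to 2404 higher and 1950 to 2327 lower on both gels, and 3739 to 4546 with a 20 kPa mean between the others. On simulated counts with 2 libraries per group, 72% of 1.5-fold changes were recovered, and other depths and group sizes were not tested.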

Other observations

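No test of an explanation is reported in this part, and the lists below were fixed in advance.

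Genes of fat cells differed between the gels, and most of those that did were lower on 20 kPa. Fabp4, a fatty acid carrier of fat cells, was at 7.58 ± 2.1 CPM on glass, 63.7 ± 4.5 CPM on 1 kPa and 27.1 ± 1.1 CPM on 20 kPa (mean ± SD, n = 2), and Angptl4, an inhibitor of lipoprotein lipase, was at 63.8 ± 0.95, 342 ± 6.1 and 148 ± 2.1 CPM. Of 20 fatty acid and adipocyte genes, 11 rose and 7 fell on 1 kPa against glass (11 and 8 adjusted over the list alone, camera adjusted p = 0.258). The 20 kPa gel against glass had 10 that rose and 9 that fell (camera adjusted p = 0.677). Between the gels, 1 rose and 9 fell (2 and 12 adjusted over the list alone, median -0.28, camera adjusted p = 0.00214, adjusted p = 0.26 with an estimated correlation).

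Oxidative stress genes were mixed. Sod2, the mitochondrial superoxide dismutase, was at 76.1 ± 0.44, 475 ± 6.9 and 212 ± 3.8 CPM on glass, 1 kPa and 20 kPa, and catalase, Cat, at 167 ± 9.9, 86.1 ± 1.4 and 94.9 ± 6.2 CPM. Of 20 such genes, 7 rose and 9 fell on 1 kPa against glass (7 and 10 adjusted over the list alone, median -0.14 and mean 0.06, test downwards, camera adjusted p = 0.505). On 20 kPa against glass, 4 rose and 11 fell (4 and 12 adjusted over the list alone, median -0.23, camera adjusted p = 0.0224, adjusted p = 0.51 with an estimated correlation). Between the gels, 1 rose and 12 fell (2 and 13 adjusted over the list alone, median -0.23, camera adjusted p = 0.000801, adjusted p = 0.34 with an estimated correlation).

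Of 24 genes of the unfolded protein and integrated stress response, 15 fell on 20 kPa against glass. Psat1, an enzyme of serine synthesis, was at 216 ± 1.9, 135 ± 9.5 and 117 ± 2.6 CPM on glass, 1 kPa and 20 kPa, whereas the cystine transporter Slc7a11 was at 3.08 ± 0.49, 18.2 ± 0.95 and 5.01 ± 0.92 CPM. Of 24 such genes, 4 rose and 11 fell on 1 kPa against glass (median -0.15, camera adjusted p = 0.0459, adjusted p = 0.34 with an estimated correlation). This call was lost without glass replicate 1 (0.0653), 1 kPa replicate 1 (0.111), 20 kPa replicate 1 (0.0549) or 20 kPa replicate 2 (0.0539). On 20 kPa against glass, 3 rose and 15 fell (3 and 16 adjusted over the list alone, median -0.26, camera adjusted p = 0.000375, adjusted p = 0.2 with an estimated correlation). Between the gels, 0 rose and 4 fell (median -0.11, camera adjusted p = 0.00569, adjusted p = 0.27 with an estimated correlation), a call lost without 1 kPa replicate 2 (0.0502).

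A minority of lysosome genes differed between the gels. Hexa, a lysosomal hexosaminidase, was at 143 ± 1.7, 200 ± 3.2 and 245 ± 7.3 CPM on glass, 1 kPa and 20 kPa, and Tfeb, a regulator of lysosome genes, at 21.5 ± 0.97, 18.4 ± 0.2 and 26.6 ± 0.46 CPM. Of 24 lysosome and autophagy genes, 6 rose and 7 fell on 1 kPa against glass (7 and 9 adjusted over the list alone, camera adjusted p = 0.728), and 10 rose and 4 fell on 20 kPa against glass (camera adjusted p = 0.443). Between the gels, 7 rose and 0 fell (median 0.08, camera adjusted p = 0.0338, adjusted p = 0.43 with an estimated correlation). This call was lost without 1 kPa replicate 1 (0.054), 1 kPa replicate 2 (0.0805) or 20 kPa replicate 1 (0.0543).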
